A study of Mus musculus with 4 samples.

How the data were processed

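RNA was measured in regulatory T (Treg) cells, the CD4+ T cells that carry the transcription factor Foxp3, sorted from pooled spleen and lymph nodes of 6-week-old male C57BL/6 mice with a green fluorescent protein knock-in at Foxp3. Per the labels, cells positive for CD8, CD19, CD11b, CD11c or the dead-cell dye 7AAD were excluded, and Treg cells were divided into those with and without TIGIT, an inhibitory receptor of T and NK cells, on their surface. There were 4 arrays, 2 of TIGIT+ and 2 of TIGIT- Treg cells, and groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates came from separate mice or sorts, so p-values measure only the spread between these samples, which may be technical.

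RNA was extracted with TriZol and labelled with biotin with an Affymetrix GeneChip WT terminal labelling kit, per the labels' protocols. The deposited values were intensity values on a linear scale, 1 per array feature, made with Affymetrix Power Tools and RMA (background correction, normalization between arrays and summary of probes) per the submitters' processing notes. Versions, and which arrays were normalized together, are not given in the sources used here. No detection call was used, so a dim feature may hold mostly background, and the fold of a gene that is dim in 1 group may be compressed.

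The log2 of each deposited intensity was taken with no pseudocount and no further normalization. Of 25194 features, 21181 had 1 gene symbol in the platform annotation, 1379 had several and 2634 were not in it. Of the features with 1 symbol, 21097 matched the RefSeq gene table of assembly GRCm38.p6 by Entrez ID, and 0 symbols changed; that table served only for names, gene types and neighbouring genes, and no coordinates are given because the sources used here name no genome build. No gene was named from a feature with several symbols. Where a gene had more than 1 feature (909 of 19537 genes), the one with the highest mean was used. The 25% of genes with the lowest mean over all arrays (4885 genes, mean intensity up to 52.65) were left out, which left 14652 genes.

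Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, 2 residual degrees of freedom and 4.97 prior degrees of freedom), with Benjamini-Hochberg adjustment and an adjusted p under 0.05 as the threshold. Differences are log2 TIGIT+ minus TIGIT-, given ± the moderated standard error. The median standard error was 0.11, which gives a 95% half-width of 0.27 log2; the number of arrays limits this precision. An exact permutation test of 2 against 2 arrays cannot reach 0.05. Gene lists (26, fixed before the data were examined) were tested with limma's camera at a preset correlation between genes of 0.01, two-sided, with adjustment over the lists, and again with the correlation estimated from the data. limma's fry, which asks whether a list's genes move on balance one way and compares them with no other genes, was run beside it.

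The fits were tested on simulated arrays of the same 14652 genes and spread, in which 200 genes were changed. Of 50 genes changed 1.5-fold, 15 were recovered; of 50 changed 2-fold, 45; of 50 changed 4-fold, 50; and 5 unchanged genes were called. Among 26 simulated lists of 20 genes, the 1 list raised 2-fold was called with the preset correlation. It was not called with an estimated correlation, and 0 unchanged lists were called in either way. Simulated genes varied independently, so this cannot show how often the preset correlation gives false calls where genes of a list vary together. Fewer genes were changed (200) than were called in the data (4422), so recovery there need not match the real comparison.

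The genes named were fixed by rule before the data were examined. They are Tigit and Foxp3, the 15 largest rises and 15 largest falls past the threshold without overlap between the groups' values, up to 4 members of each list with the smallest p, and a short list of 24 receptors, transcription factors and effectors. Predicted genes, receptor segments and small RNA genes were counted and not named under that rule. Rorc, Sell and Tcf7 of the short list were not measured by a feature of that gene alone here. Genes with near-identical relatives (the Lilrb4, Klr, Ifitm, Ms4a4 and Naip families) may share probes and are uncertain. Alternatives covered the filter on dim genes, quantile normalization, median centring, the mean of a gene's features, eBayes with trend and robust options, the replicate number as a block, a pseudocount of 16, leaving out each array, other thresholds and, chosen after seeing the data, cyclic loess normalization. Figures were drawn with matplotlib 3.10.9.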

Results

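The series measured gene expression in TIGIT+ and TIGIT- Treg cells from unimmunised mice on 4 arrays, 2 per group, and asks how the Treg cells that carry TIGIT differ from those that do not. Median intensity was 129.4 and 129.0 on the TIGIT- arrays and 125.1 and 124.7 on the TIGIT+ arrays. Over all features, log2 intensities correlated across features at r = 0.9934 between the TIGIT- arrays and r = 0.9966 between the TIGIT+ arrays, against 0.9737 to 0.9808 between arrays of different groups; features are not independent replicates. No array pair held the same values.

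Tigit, the gene of the receptor used for the sort, had intensities of 724 and 877 in TIGIT- cells and 5383 and 5167 in TIGIT+ cells, a log2 difference of 2.73 ± 0.12 (SE, n = 2 per group; limma adjusted p = 0.000115). Foxp3, on which both groups were gated, was bright in both, at 5300 and 4965 in TIGIT- and 4606 and 4805 in TIGIT+ cells, and its difference of -0.12 ± 0.10 did not pass (limma adjusted p = 0.376).

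Beyond the sort gene, TIGIT+ Treg cells had much higher RNA of Klrg1, an inhibitory lectin-like receptor (log2 difference 4.30 ± 0.36), Il10, an anti-inflammatory cytokine (3.82 ± 0.21), and Fgl2, a secreted effector of Treg cells (3.06 ± 0.14). Higher too were Gzmb, a cytotoxic protease (2.86 ± 0.20), Prdm1, which encodes the transcription factor Blimp-1 (2.78 ± 0.13), and Havcr2, the inhibitory receptor TIM-3 (2.78 ± 0.14). The same cells had much lower RNA of Dapl1 (-4.24 ± 0.19), Igfbp4, an insulin-like growth factor binding protein (-3.71 ± 0.11), and Satb1, a chromatin organiser of T cells (-1.96 ± 0.11). The remaining genes of the 15 largest rises were Sccpdh (3.58), Lilrb4a (3.17), Ttc39c (3.11), Cxcl2 (2.95), Gcnt1 (2.88), Cybb (2.87), Cysltr2 (2.86), Tigit itself and Mki67 (2.67). The remaining falls were Ms4a4c (-2.67), Cnn3 (-2.64), Ifitm3 (-2.46), Gata1 (-2.39), Treml2 (-2.28), Sorcs2 (-2.11), Cd7 (-2.09), Snhg17 (-1.94), Amigo2 (-1.77), Sgk3 (-1.75), Gpr146 (-1.71) and St8sia1 (-1.69). Each of these genes passed at a limma adjusted p of 0.00223 or lower, with no overlap between the groups' values. Cxcl2 and Havcr2 lay below the dim limit in TIGIT- cells, so their folds may be compressed. Another 11 genes with falls of such size were predicted or small RNA genes.

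**Figure D1:**
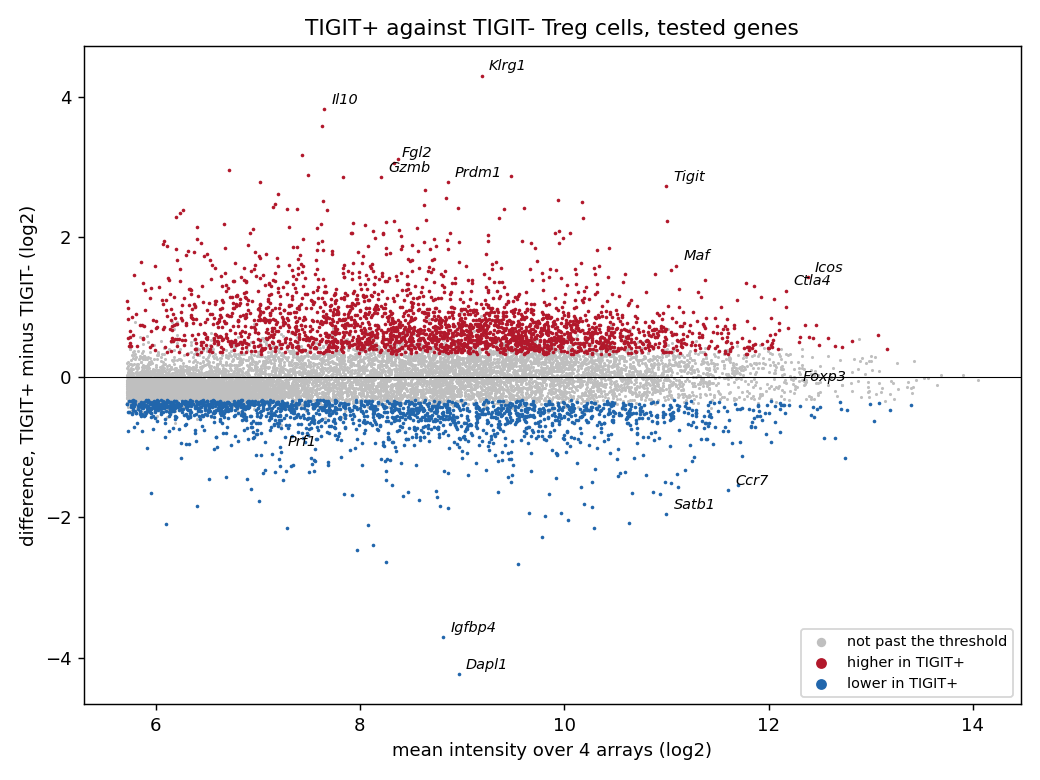
Each point is 1 of 14652 tested genes, with mean log2 intensity over 4 arrays on the x axis and the log2 difference, TIGIT+ minus TIGIT-, on the y axis; red and blue points passed a limma adjusted p of 0.05. Klrg1 (4.30) and Il10 (3.82) had the largest rises, Dapl1 (-4.24) and Igfbp4 (-3.71) the largest falls, and Foxp3 lay at -0.12.

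In all, 4422 of 14652 genes (30.2%) passed, 2571 higher and 1851 lower in TIGIT+ cells (58.1% higher). Of these, 651 differed at least 2-fold, 516 higher and 135 lower, and 73 at least 4-fold, 60 higher and 13 lower. The split depends on the scaling: centring each array on its median shifted every gene by -0.14 log2 and gave 1871 higher and 4683 lower (28.6% higher). Small differences are relative to that shift, which moved the median difference of tested genes from -0.057 to -0.20. Quantile normalization gave 52.85% higher, and cyclic loess, chosen after seeing the data, gave 61.48%. Without TIGIT+ replicate 1 the count was 1245, and without TIGIT+ replicate 2 it was 1930.

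Many receptors and effector molecules of Treg cells were higher in TIGIT+ cells. Of 18 tested suppressive effector molecules, 11 rose and 2 fell (12 and 2 adjusted over the list alone), with a mean difference of 1.07. Besides Il10, Fgl2 and Gzmb, the rises included Itgb8, an integrin chain that takes part in activating TGF-beta (5.65-fold). Prf1, the pore-forming protein perforin, fell by 1.06 ± 0.12 log2. The list passed camera (limma adjusted p = 7.87e-05; adjusted p = 0.288 with an estimated correlation). Of 18 genes of the co-inhibitory receptor list, 9 rose and 2 fell (9 and 3 adjusted over the list alone). These counts include ligand genes: Pdcd1lg2 (0.98 ± 0.14) and Cd274 (0.56 ± 0.11) rose and Lgals9 (-0.60 ± 0.11) fell. The list mean was 0.83 (limma camera adjusted p = 0.0031; adjusted p = 0.406 with an estimated correlation). Receptor genes of the list that rose included Pdcd1, which encodes PD-1 (2.09 ± 0.18), Cd200r1 (2.03 ± 0.12), Lag3 (1.37 ± 0.11) and Ctla4 (1.23 ± 0.12). Cd96, a receptor that shares a ligand with TIGIT, fell by 0.40 ± 0.10. It did not pass after quantile normalization (adjusted p = 0.075) or without TIGIT+ replicate 1 (adjusted p = 0.203) or 2 (adjusted p = 0.129). Cd226, their activating counterpart, differed by -0.21 ± 0.13 and did not pass. Of 15 genes of the co-stimulatory receptor list, which also holds the ligand gene Cd40lg, 10 rose and 1 fell (10 and 2 adjusted over the list alone). The mean was 0.49, and Tnfrsf8 (2.23 ± 0.16), Icos (1.43 ± 0.10), Tnfrsf1b (1.39 ± 0.13) and Tnfrsf9 (1.10 ± 0.12) were among the rises. That list passed camera (limma adjusted p = 0.00676; adjusted p = 0.288 with an estimated correlation), but not with the dimmest 50% of genes left out (adjusted p = 0.0683).

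Of 28 core Treg genes, 17 rose and 5 fell, the same counts as adjusted over the list alone. The mean difference of the list was 0.63 (limma camera adjusted p = 0.00126; adjusted p = 0.288 with an estimated correlation). Itgae, the integrin CD103 (1.61 ± 0.11), Ikzf2, the transcription factor Helios (1.11 ± 0.11), and Nrp1 (0.80 ± 0.14) rose, Nrp1 without TIGIT+ replicate 1 having an adjusted p of 0.0624. Gpr83 fell by 1.63 ± 0.10 and Ecm1 by 1.32 ± 0.10. Il2ra, the IL-2 receptor alpha chain, passed at -0.35 ± 0.10 (limma adjusted p = 0.0417). It did not pass after quantile normalization (adjusted p = 0.19), cyclic loess (0.109) or without the filter on dim genes (0.0517), nor without any single array (adjusted p 0.0513 to 0.29). Some members of the core Treg, co-inhibitory, suppressive effector and Th1-associated lists were known beforehand as genes that the study of this series discussed. These lists, though fixed before the data were examined, are therefore not independent evidence of direction. The same holds for such genes of the short list, for example Il10 and Fgl2.

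**Figure D2:**
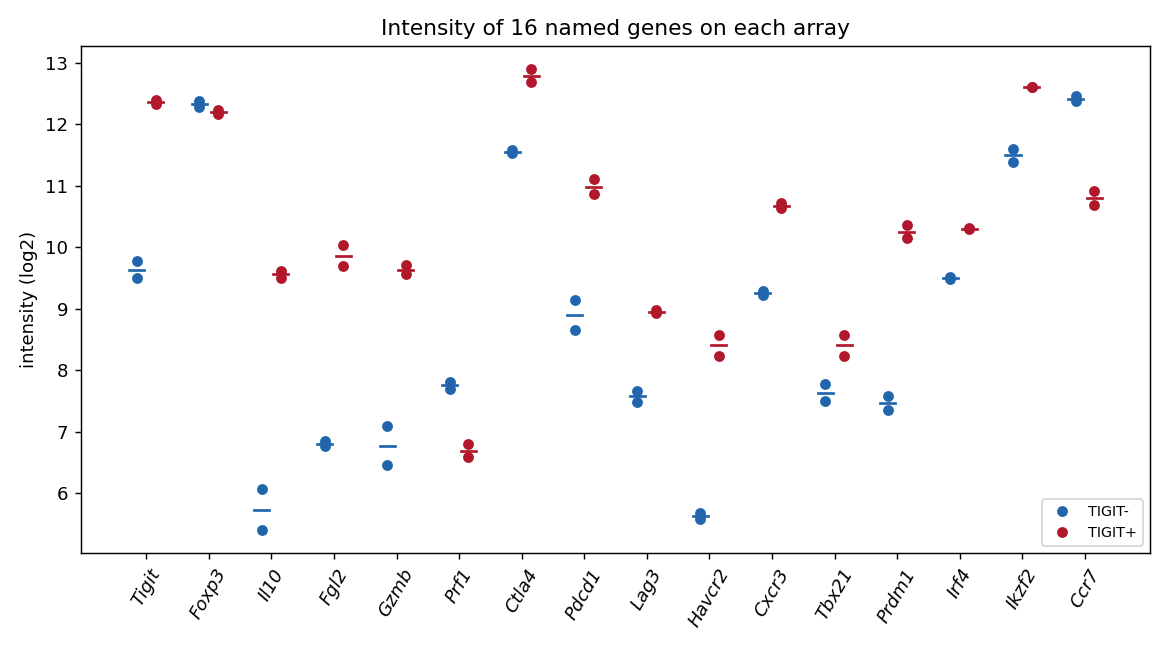
Log2 intensity of 16 named genes on each array, with TIGIT- arrays as blue points, TIGIT+ arrays as red points and bars at the group means (n = 2 per group). Foxp3 had intensities between 4606 and 5300 on all 4 arrays, while Il10 rose from 42.4 and 67.1 to 788.5 and 723.1 and Ccr7 fell from 5606 and 5309 to 1938 and 1649.

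Genes of naive and resting T cells were lower in TIGIT+ cells: 18 of 23 tested members fell and 0 rose, the same counts as adjusted over the list alone. Over the list the mean was -1.02 (limma camera adjusted p = 2.34e-08; adjusted p = 0.288 with an estimated correlation). Besides Dapl1, Igfbp4 and Satb1, Ccr7, the lymph node homing receptor, fell by 1.61 ± 0.12, and Bcl2, an inhibitor of apoptosis, fell by 0.99 ± 0.11. Of 13 conventional CD4 T cell markers, 8 fell and 1 rose (9 and 1 adjusted over the list alone). Its members averaged -1.10 (limma camera adjusted p = 0.000195; adjusted p = 0.288 with an estimated correlation). Dapl1, Igfbp4 and Satb1 stand in both lists. Pde3b, which lay below the dim limit in TIGIT+ cells, fell by 1.65 ± 0.18.

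Of 26 chemokine receptors and homing molecules, 17 rose and 5 fell (17 and 6 adjusted over the list alone). The list mean was 0.70 (limma camera adjusted p = 3.35e-05; adjusted p = 0.288 with an estimated correlation). Ccr8 (2.27 ± 0.11), Ccr3 (1.88 ± 0.14), Cxcr3 (1.42 ± 0.10) and Ccr6 (1.22 ± 0.13) rose, while Ccr9, a gut homing receptor, fell by 1.26 ± 0.17.

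Transcription factors of effector Treg cells were higher, 12 of 19 rising and 0 falling (13 and 0 adjusted over the list alone). The mean difference of the list was 0.96 (limma camera adjusted p = 1.38e-07; adjusted p = 0.288 with an estimated correlation). After Prdm1, the examples were Bhlhe40 (2.27 ± 0.17), Rora (1.75 ± 0.13), Maf (1.59 ± 0.11) and Irf4 (0.80 ± 0.10). Follicular helper and follicular Treg genes rose in 11 of 15 cases and fell in 0 (12 and 0 adjusted over the list alone). Over the list the mean was 0.90 (limma camera adjusted p = 1.00e-07; adjusted p = 0.288 with an estimated correlation). Members included Tox2 (1.56 ± 0.11), Sh2d1a (1.21 ± 0.10) and Bcl6 (0.89 ± 0.15). Of 16 Th1-associated genes, 8 rose and 1 fell, as also adjusted over the list alone. Its members averaged 0.65 (limma camera adjusted p = 0.00101; adjusted p = 0.406 with an estimated correlation). They included Ifng (1.69 ± 0.11), Il18r1 (1.54 ± 0.10), Il18rap (1.33 ± 0.11) and the transcription factor Tbx21 (0.77 ± 0.15; adjusted p = 0.0726 without TIGIT+ replicate 2). Of 12 Th2-associated genes, 5 rose and 1 fell, as also adjusted over the list alone. The list mean was 0.71 and the median 0.19 (limma camera adjusted p = 0.0169; adjusted p = 0.477 with an estimated correlation). The 5 were the receptor genes Ccr8, Cd200r1, Il17rb (1.94 ± 0.10), Ccr3 and Ccr4 (the last named after its value was seen). Gata3, the Th2 transcription factor, differed by 0.24 ± 0.14 and did not pass. With the dimmest 50% of genes left out the Th2 list had an adjusted p of 0.0597. Of 13 Th17-associated genes, 5 rose and 2 fell (5 and 3 adjusted over the list alone) and the list did not pass (mean 0.35, limma camera adjusted p = 0.219); Il23r (1.87 ± 0.20), Rora (1.75 ± 0.13), Ccr6 and Ahr (1.07 ± 0.11) rose, Il23r from below the dim limit.

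**Figure D3:**
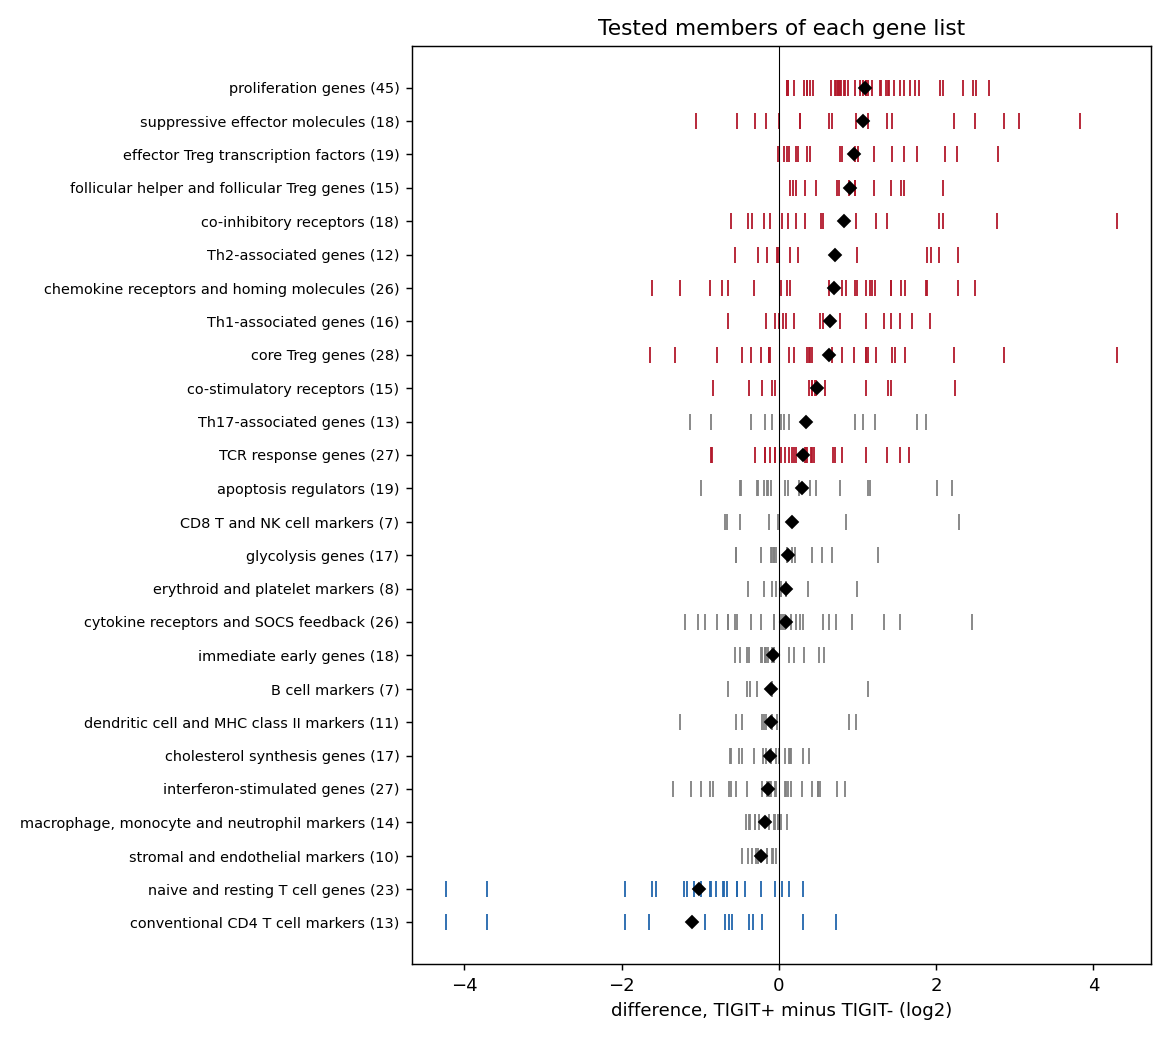
Log2 difference, TIGIT+ minus TIGIT-, of each tested member (ticks) and the mean (diamonds) of 26 gene lists, with the number of tested members in brackets; red and blue lists passed camera at the preset correlation, upwards and downwards. The means ran from -1.10 for conventional CD4 T cell markers to 1.09 for proliferation genes.

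Proliferation genes rose in 36 of 45 cases and fell in 0 (40 and 0 adjusted over the list alone). The mean difference of the list was 1.09 (limma camera adjusted p = 6.12e-14; adjusted p = 0.454 with an estimated correlation). Mki67, the marker Ki-67, rose by 2.67 ± 0.33, Kif11 by 2.51 ± 0.29, Ncapg by 2.47 ± 0.23 and Ccna2 by 2.05 ± 0.24. The TIGIT+ arrays differed here, with a mean log2 intensity over the list of 8.68 in replicate 1 and 8.13 in replicate 2, both above the 7.31 of each TIGIT- array.

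Of 27 T cell receptor response genes, 9 rose and 2 fell (11 and 3 adjusted over the list alone). Over the list the mean was 0.31 (limma camera adjusted p = 0.0134; adjusted p = 0.288 with an estimated correlation). Rgs16 (1.53 ± 0.13) rose and Myc fell by 0.85 ± 0.10. This list missed the threshold with the dimmest 50% left out (adjusted p = 0.152) and after cyclic loess (adjusted p = 0.0598), an alternative chosen after seeing the data. Of 26 genes of the list of cytokine receptors and SOCS genes, which also holds the receptor antagonist gene Il1rn, 7 rose and 9 fell. The counts adjusted over the list alone were the same (mean 0.09, limma camera adjusted p = 0.784). Il1r2, a decoy receptor for IL-1, rose by 2.46 ± 0.13 and Socs3 fell by 1.03 ± 0.11. Of 18 immediate early genes, which respond to tissue handling, 1 rose and 3 fell (0 and 3 adjusted over the list alone; mean -0.08, limma camera adjusted p = 0.378), with Ier2 at -0.55 ± 0.10 (adjusted p = 0.0713 without TIGIT+ replicate 1 and 0.0788 without replicate 2). Of 19 apoptosis regulators, 5 rose and 3 fell (7 and 4 adjusted over the list alone; mean 0.29, limma camera adjusted p = 0.378), with Casp1 at 2.20 ± 0.16, Casp4 at 2.01 ± 0.17 and Bcl2 at -0.99 ± 0.11. Of 27 interferon-stimulated genes, 5 rose and 9 fell, as also adjusted over the list alone (mean -0.14, limma camera adjusted p = 0.38), with Oasl2 at -1.34 ± 0.14 and Usp18 at -1.11 ± 0.13. Glycolysis genes rose in 3 and fell in 2 of 17 cases (4 and 2 adjusted over the list alone; limma camera adjusted p = 0.401), with Aldoc at 1.25 ± 0.18. Cholesterol synthesis genes rose in 0 and fell in 2 of 17 cases (0 and 1 adjusted over the list alone; limma camera adjusted p = 0.38). The list passed downwards without TIGIT- replicate 1 (mean -0.33, adjusted p = 0.0151).

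Apart from the conventional CD4 T cell markers, no list of markers of other cells that a sort could hold passed camera at the preset correlation on all 4 arrays. Small negative means of dim lists are to be read against a shift among dim genes. The 1190 olfactory and vomeronasal receptor genes, taken without the filter, had a median difference of -0.15 and a median TIGIT- intensity of 26.49. All genes, without the filter, were also grouped by mean log2 intensity. The median difference was -0.13 in the dimmest group (mean 4.15), -0.16 at 6.69 and -0.07 at 7.36. It was 0.06 at 8.19, 0.13 at 9.73 and 0.07 in the brightest group (11.01). The negative shift thus does not extend to bright lists. Of 7 tested B cell markers, 1 rose and 2 fell (1 and 3 adjusted over the list alone; limma camera adjusted p = 0.277, fry adjusted p = 0.0122), with Cd22 at 1.13 ± 0.21 and Bank1 at -0.64 ± 0.10 (adjusted p = 0.052 without TIGIT+ replicate 2). Of 7 CD8 T and NK cell markers, 2 rose and 2 fell (2 and 3 adjusted over the list alone). The mean was 0.17, the median -0.13 and the camera direction down (limma adjusted p = 0.791), so these differ in sign. Klrb1c, the NK cell receptor NK1.1, rose by 2.29 ± 0.14 from below the dim limit, Nkg7 rose by 0.85 ± 0.19, and Cd8b1 fell by 0.66 ± 0.12. Without TIGIT+ replicate 1, the adjusted p was 0.0781 for Nkg7 and 0.0783 for Cd8b1, and without TIGIT+ replicate 2 it was 0.0698 for Nkg7. Of 14 macrophage, monocyte and neutrophil markers, 0 rose and 2 fell (0 and 0 adjusted over the list alone; mean -0.18, limma camera adjusted p = 0.0914; 0.0429 without TIGIT- replicate 2). Dendritic cell and MHC class II markers rose in 2 and fell in 3 of 11 cases, as also adjusted over the list alone (limma camera adjusted p = 0.378); Cd74 was at 0.98 ± 0.15. Of 8 erythroid and platelet markers, 2 rose and 1 fell, as also adjusted over the list alone (limma camera adjusted p = 0.775). Of 10 stromal and endothelial markers, 0 rose and 1 fell, as also adjusted over the list alone (mean -0.23, limma camera adjusted p = 0.0697; 0.0389 without TIGIT+ replicate 2).

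Of the 26 lists, 13 passed camera with the preset correlation, 11 upwards and 2 downwards, and 0 passed with an estimated correlation (2 at an unadjusted p under 0.05). The upward lists share many of their rises, so their passes are not separate findings. Gzmb, Penk, Nt5e, Ebi3 and Entpd1 stand in the core Treg and the suppressive effector lists. Lag3, Itgb8, Icos, Pdcd1, Ccr8, Ccr3, Ccr4, Cd200r1 and Maf also stand in more than 1 list. limma's fry called 15 lists. It did not call the proliferation genes (fry adjusted p = 0.086), and it called the Th17, apoptosis and B cell lists, which camera did not. With 2 residual degrees of freedom, the estimated-correlation test did not call the list raised 2-fold in the simulation. Genes there varied independently, whereas the proliferation list had an estimated correlation of 0.72, so the simulation does not vouch for calls at the preset correlation.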

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

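The tests of explanations in this part, the splits of the arrays included, were chosen after the results were seen. Features that name no single gene stood outside the comparison of genes. Each of these sets was fitted and adjusted on its own, with no filter on dim features, so the counts are not comparable with those of the genes. Of 2634 features not in the probe annotation, 145 were higher and 373 lower in TIGIT+ cells (median difference -0.14). Of 1379 features with several symbols, 75 were higher and 228 lower (median -0.21). Over all genes without the filter, the median was -0.088, so part of the excess of falls may be a shift among dim features. The most raised unannotated feature was 10503098 (log2 difference 3.23 ± 0.15) and the most lowered 10406852 (-3.13 ± 0.34). Among features with several symbols these were 10494001 (2.18 ± 0.40) and 10403821 (-4.415 ± 0.18), the last a larger fall than that of Dapl1 (-4.24). All of these features were named after their values were seen. The number of genes past the threshold was 4422 in the real division of the arrays and at most 0 in the others (17 and 5 at an unadjusted limma p under 0.05); the real one was 1 of 3 possible splits, too few for a share under 0.05.

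Small non-coding RNA genes were lower in TIGIT+ cells: of 52 tested, 38 fell and 2 rose, with a median of -1.14 (-1.06 to -1.28 under the other scalings). A difference that follows intensity is argued against, since 10000 lists of other genes matched on intensity had a median of 0.032, with 95% of them between -0.10 and 0.18. Lower host gene RNA does not account for the whole fall of the 26 small RNA genes inside a tested host gene: their median was -0.62, and that of the 23 host genes was -0.069 (95% bootstrap interval -0.34 to 0.04), although 8 hosts fell. Small RNA genes inside host genes that were not tested, most of which fell, stood outside this check. Lower recovery of small RNA from the TIGIT+ preparations stays open, because all 10 small RNA genes outside any gene fell (median -1.26) and preparation and group cannot be told apart; replicates differed by a median of 0.07 and 0.02. A difference in small RNA content between the cell populations also stays open and was not tested.

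Some genes higher in TIGIT+ cells are known from NK or myeloid cells (Klrg1, Klrb1c, Cybb, Lilrb4a), although Klrg1 also stands in the core Treg list used here. Myeloid cells in the TIGIT+ sort are argued against: the 14 tested myeloid markers had a median of -0.19 (-0.03 to -0.33 under the other scalings), and the sort excluded CD11b+ and CD11c+ cells. That median is close to the -0.15 of olfactory and vomeronasal receptor genes, so it shows the absence of a rise and no clear loss. NK cells are argued against as well: of Ncr1, Klrd1, Klrk1, Klre1, Klrc1, Klra8, Tyrobp and Eomes, the highest upper 95% limit of a difference was 0.38. Apart from Tyrobp and Eomes, these genes were left out of the main comparison as dim. The CD4+ Foxp3+ gate would remove NK cells. Expression of these genes by TIGIT+ Treg cells themselves is a hypothesis, found and examined on the same arrays.

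Genes of naive T cells were lower in TIGIT+ cells. A trend with intensity is argued against, as the list's mean was -1.02 after cyclic loess. Foxp3-negative T cells in the TIGIT- sort could lower Foxp3 there, although the CD4+ Foxp3+ gate of both groups would remove them. Foxp3 was, if anything, higher in TIGIT- cells (5300 and 4965 against 4606 and 4805), opposite to that prediction, but its difference of -0.12 has a 95% interval of -0.37 to 0.12, whose upper limit allows up to 7.99% of such cells. The median fallen gene of the list would need 6.13% even if those cells reached the brightest value on the arrays. Any dimmer profile would need a larger share. For 6 of 18 fallen genes the needed share exceeded the allowed one, so such cells alone fall short for these 6, if Treg cells of both groups hold equal Foxp3. The other fallen genes need no more than the allowed share at that profile, so this explanation cannot be told apart for the list. A more activated state of TIGIT+ Treg cells stays open and was not tested.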

How the results depend on the processing

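No alternative turned the direction of a called result. The count of genes (4422; 2571 higher, 1851 lower) became 651 (516 and 135) with at least a 2-fold difference required as well, and 2217 (1623 and 594) under a 1.5-fold rule with no test. The lower count was 2993 at an adjusted p under 0.1 and 4683 under median centring; the cause of the last was its shift of every gene by -0.14. Leaving out 1 array gave 1245 to 5105 genes, 924 to 2917 higher and 321 to 2188 lower; the lone array is then assumed to vary like the other group. The lowest counts came without a TIGIT+ array, where the spread was taken from the 2 TIGIT- arrays alone. Over all features, those arrays differed by a median of 0.14 log2, against 0.10 between the TIGIT+ arrays. The low counts thus go with the wider spread of the TIGIT- pair and need not reflect the TIGIT+ array left out. The count at 2-fold stayed between 543 and 823 over the filters, scalings, variance models and left-out arrays. Of 121 genes named by rule, 22 lost their call without TIGIT+ replicate 1, 20 without TIGIT+ replicate 2 and at most 6 under the other scalings, variance models and left-out arrays or with no filter. With the lowest 50% left out, only 99 of them were tested, and 0 of these lost their call. Cyclic loess, chosen after seeing the data, gave 3928 genes. Of the 26 lists, 13 passed with the preset correlation and 0 with an estimated one. The replicate numbers are shared by only 2 pairs and were not taken as pairing: deviations of same-numbered arrays correlated at 0.17 across genes, and the replicate block gave 5365 genes. Intensity near background limits what dim genes can show.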

Other observations

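The families and single genes of the next sentences were chosen after the values were seen; the 2 hypothesis tests at the end were set before their genes were looked at. Gene families grouped by symbol showed other shifts. Of 34 tested genes with the symbol stem Rpl (ribosomal proteins of the large subunit), 20 fell and 0 rose (median -0.39). Of 30 with the stem Rps (small subunit), 16 fell and 1 rose (median -0.37). The Rps stem was not limited to ribosomal proteins, as Rps6k kinase genes carry it too. Both medians stayed below 0 under each scaling tried (-0.27 to -0.53). Ndufa genes, subunits of respiratory complex I, fell in 6 and rose in 0 of 14 cases (median -0.33). Centrosomal Cep genes rose in 18 and fell in 0 of 35 cases (median 0.41), and kinesin Kif genes rose in 17 and fell in 0 of 34 (median 0.38); these medians too kept their sign under each scaling tried. Among 227 families of at least 8 tested genes, 17 passed limma's camera with the preset correlation. With an estimated one, 0 passed (3 at an unadjusted p under 0.05), and the camera adjusted p was 0.815 for each of the 5 families above. The 17 also held olfactory receptor genes (Olfr, 13 of 156 fell and 0 rose, median -0.17, limma camera adjusted p = 0.00193). Collagen genes passed as well (Col, 3 of 42 fell and 0 rose, median -0.23, limma camera adjusted p = 0.00131). A pass at the preset correlation can thus rest on a small shift.

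Genes outside the fixed lists, chosen after their values were seen, rose in TIGIT+ cells as well. They include Nrn1 (2.53 ± 0.13), Npas4 (2.19 ± 0.12), Alcam (2.13 ± 0.10), Cxcl10 (2.06 ± 0.17), Epcam (2.05 ± 0.30), the growth factors Hgf (1.84 ± 0.14) and Fgf2 (1.61 ± 0.11), and the receptor kinase Axl (1.56 ± 0.16).

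The inflammasome sensors Naip5 (2.40 ± 0.12), Naip6 (2.13 ± 0.11) and Naip2 (1.67 ± 0.10) rose with Casp1, Casp4 and Il18 (1.64 ± 0.24), and Naip genes may share probes. The hypothesis that other inflammasome genes rise with them was tested on 10 genes not looked at before, of which 6 were tested. Nlrp1b (1.11 ± 0.24; adjusted p = 0.0836 without TIGIT+ replicate 1) and Aim2 (0.82 ± 0.12) rose, the median was 0.0498 (95% bootstrap interval -0.21 to 0.97), and the test decides nothing.

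The feedback genes Socs1 (-1.19 ± 0.18), Socs3 (-1.03 ± 0.11), Socs2 (-0.78 ± 0.12) and Cish (-0.65 ± 0.12) fell with Bcl2 and Myc, though Cish had an adjusted p of 0.0819 without TIGIT+ replicate 1. These are targets of STAT5, the factor that acts downstream of IL-2. The hypothesis that other STAT5 targets fall with them was tested on 6 genes not looked at before. Osm (-0.92 ± 0.15) and Ccnd3 (-0.59 ± 0.13) fell while Cdk6 rose (1.22 ± 0.11), Ccnd3 having an adjusted p of 0.126 without TIGIT+ replicate 2, and the median was -0.099 (95% bootstrap interval -0.76 to 0.70). The rule set beforehand, a median above -0.1, was met, and by its terms this counts against the hypothesis. It was met by far less than the bootstrap interval, which was not part of that rule. With that interval taken into account, the result does not settle the question.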
